A study of Ovis aries with 42 samples.

How the data were processed

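RNA sequencing of liver and gallbladder from wild-type (WT) sheep and from sheep with a disrupted CFTR gene (CF) was analysed. CFTR encodes the epithelial chloride and bicarbonate channel that is defective in cystic fibrosis. Total RNA was extracted from frozen tissue with TRIzol after homogenisation with beads, per the labels. The liver series held 24 libraries, with 2 of each genotype at gestation day 50, 65, 80, 100 and 120 (d50 to d120) and 2 of each genotype at the end of gestation. The gallbladder series held 12 libraries, 2 each of WT at d100, d120 and birth and of CF at d80, d100 and d120. Among the RNA libraries newborn animals are called term in the WT liver labels and birth elsewhere, and these were read as 1 stage. The 6 chromatin accessibility libraries of the series were not analysed here.

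The values in both deposited tables are estimated counts per gene, one column per library, and their totals differ between libraries as unscaled counts do. The gallbladder table is a merged salmon gene count sheet per the file headers, and 87.8% of its values above 0 were whole within 0.001. The name of the liver table mentions TPM, but its column totals ran from 29705597 to 56808639 counts, and 87.5% of its values between 0.5 and 1.5 lay within 0.1 of 1. It was therefore read as estimated counts, of which 0.3% of those above 0 were whole within 0.001. A rescaling of the liver values by transcript length is not excluded. Per the labels, the processing tools of the RNA libraries included STAR 2.7.9a, Salmon 1.10.1 and 1.9.0, edgeR, limma and DESeq2, with no role stated. The genome build and annotation behind the RNA counts are not given in the sources used here, so no gene positions are given. There were 29285 genes in the gallbladder table and 22981 genes in that of liver. Genes named only by a locus number were given a symbol from a gene table of the sheep reference where the number matched, 508 in gallbladder and 127 in liver.

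Estimated counts were rounded to whole numbers and each tissue was fitted by itself in edgeR 4.0.16 (R 4.3.3). TMM factors, filterByExpr on the groups and a quasi-likelihood model with one mean per genotype and stage over all libraries of the tissue were used. Tests were two-sided, and p-values were adjusted over all genes tested by the Benjamini-Hochberg method with a threshold of 0.05. Log2 fold changes are given with a standard error computed from the fold change and its F statistic. Levels are counts scaled to a common library total with TMM factors (CPM), with the standard deviation (SD) over libraries. The mean genotype contrast of a tissue is the average of the CF minus WT contrasts at its stages with both genotypes, leaving out the end of gestation in liver. Age slopes are linear in gestation day within the fetal stages and are given as the change on the fitted line from d50 to d120. A fold against a group without a single count was computed against a floor of 3 counts over the group and is a lower bound. Floors and standard errors of single libraries cover counting error only.

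Before the data were examined, 36 gene lists were fixed, of which 34 had at least 5 genes tested; the lists of mitochondrially encoded and sex-linked genes matched no gene in either table. Lists were tested with camera of limma 3.58.1 with a preset correlation of 0.01, with an adjusted p over the lists of a contrast. Camera compares a list with all other genes. The same test with a correlation estimated from the data was run beside it, and fry, which asks whether the members move on balance in 1 direction without comparing them with other genes. List tests were planned for 7 contrasts and added for the 9 others after the data were seen. Several lists share genes with one another, and none was chosen on these samples.

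Named genes were chosen by a rule fixed before the data were examined. CFTR came first. For each mean genotype contrast, the 10 genes with the largest change in each direction were taken among those past the threshold, with a mean of at least 1 CPM, a gene symbol and the same direction at every stage. Other contrasts had 5 genes per direction, chosen in the same way except for the condition on stages. Where fewer than 5 passed, the genes with the smallest p were taken, and those past the threshold are stated as such. Up to 4 members per list with the smallest p were added.

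Every count of genes was recomputed under other settings. For all contrasts these were DESeq2 size factors, the DESeq2 1.42.0 Wald test, no filter on low counts, and each library of the contrast left out in turn. For the 2 mean genotype contrasts alone they were also an additive model of genotype and stage and 1 unit per donor-number stem. A voom fit with the stem as a block was run for the liver mean alone. Where a library was left out of a pair, the remaining one was assumed to vary like the other groups. Settings added after the data were seen were a hepatocyte covariate, genes low in liver alone, 2 doubted gallbladder libraries left out, and the d100 gallbladder pairs summed. The pipeline was tested on simulated data with 200 changed genes per contrast and on regrouped samples. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

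Depth ran from 29705597 to 56808639 estimated counts per library in liver and from 32374693 to 54443213 estimated counts in gallbladder, and 16508 and 18717 genes were tested. Donor numbers show that some libraries of a pair share a stem and that some animals gave both tissues. The labels give 1 stem to both a WT d65 and a CF d100 liver library, and which label is right is not known. No pair was close enough to be read as 1 library sequenced again. The column names of the CF d100 gallbladder pair do not show whether they are 2 animals. The WT term liver libraries carry library numbers apart from all other liver libraries, so a batch and the genotype cannot be told apart at the end of gestation. The labels give no dates, sexes or sequencing runs.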

Results

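The liver libraries covered 5 fetal stages and the end of gestation in both genotypes, and the gallbladder libraries covered d80 to birth with 2 stages, d100 and d120, held by both genotypes. Each group had 2 libraries, so a group mean stands with an SD of n = 2 unless another n is given. The study's title places the work in early hepatobiliary disease of CFTR-deficient sheep, and the genotype contrasts ask which transcripts differ in that setting. The first 3 principal components of the 1000 most variable genes held 48.3%, 10.4% and 8.48% of the variance in liver and 49%, 28.6% and 8.77% in gallbladder. Rank correlations across genes between the libraries of a pair ran from 0.937 to 0.986 in liver. In gallbladder they ran from 0.923 to 0.993 except for the CF d80 pair, at 0.833.

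CFTR transcript rose with age in CF liver and was higher in CF than in WT liver at the end of gestation. In WT liver it stayed between 1.22 ± 0.448 CPM at d50 and 1.93 ± 1.25 CPM at d120, and it was 1.33 ± 0.679 CPM at term. In CF liver it was 0.874 ± 0.264 CPM at d50, 1.14 ± 0.523 at d65, 4.31 ± 0.661 at d80, 4.35 ± 1.86 at d100, 11.7 ± 7.93 at d120 and 40.3 ± 2.68 at birth. The rise with age in CF liver was 13.2-fold from d50 to d120 on the fitted line (log2 3.72 ± 0.51, adjusted p = 0.000132, edgeR), and CF birth exceeded WT term 30.3-fold (log2 4.92 ± 0.61, adjusted p = 1.49e-05). A library batch cannot be told apart from genotype at the end of gestation. Cholangiocyte markers also leaned higher in CF birth, KRT7 by more than CFTR (below), so a higher share of bile duct cells was not separated from genotype either. The mean fetal contrast, log2 0.87 ± 0.24, missed the threshold with an adjusted p of 0.0636, and so did the difference between the 2 slopes, log2 3.18 ± 0.69 with an adjusted p of 0.199. The fetal mean passed without WT d120 replicate 2 (log2 1.05, adjusted p = 0.0287) and without CF d120 replicate 2 (log2 0.99, adjusted p = 0.0338), within a range of 0.000235 to 0.653 over 27 alternatives. It also passed without the filter on low counts (adjusted p = 0.0358) and with the DESeq2 Wald test (0.0122), which called the slope difference as well (log2 3.16, adjusted p = 0.00512). At d120 alone CFTR missed by edgeR (log2 2.58 ± 0.55, adjusted p = 0.0867) and passed by DESeq2 (0.00107) and without the filter (0.0323). In gallbladder CFTR was 4.48-fold higher in CF over d100 and d120 (log2 2.16 ± 0.54, adjusted p = 0.0154), with 7.83 ± 0.984 and 11.4 ± 0.102 CPM in WT against 43.7 ± 4.90 and 40.9 ± 15.4 CPM in CF. That call was lost without WT d100 replicate 1 (adjusted p = 0.067), WT d100 replicate 2 (0.0554) or CF d100 replicate 2 (0.0544), within 0.000289 to 0.206 over 18 alternatives. It was also lost with genes low in liver alone, rescaled on them, a setting chosen after seeing the data, where the difference was 1.89-fold (log2 0.92 ± 0.54, adjusted p = 0.206) with the same standard error. The WT gallbladder libraries of these stages held hepatocyte genes at 29.1% to 67.5% of their WT liver level. The labels do not state the kind of mutation, so the transcript level does not check the genotype.

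**Figure D1:**
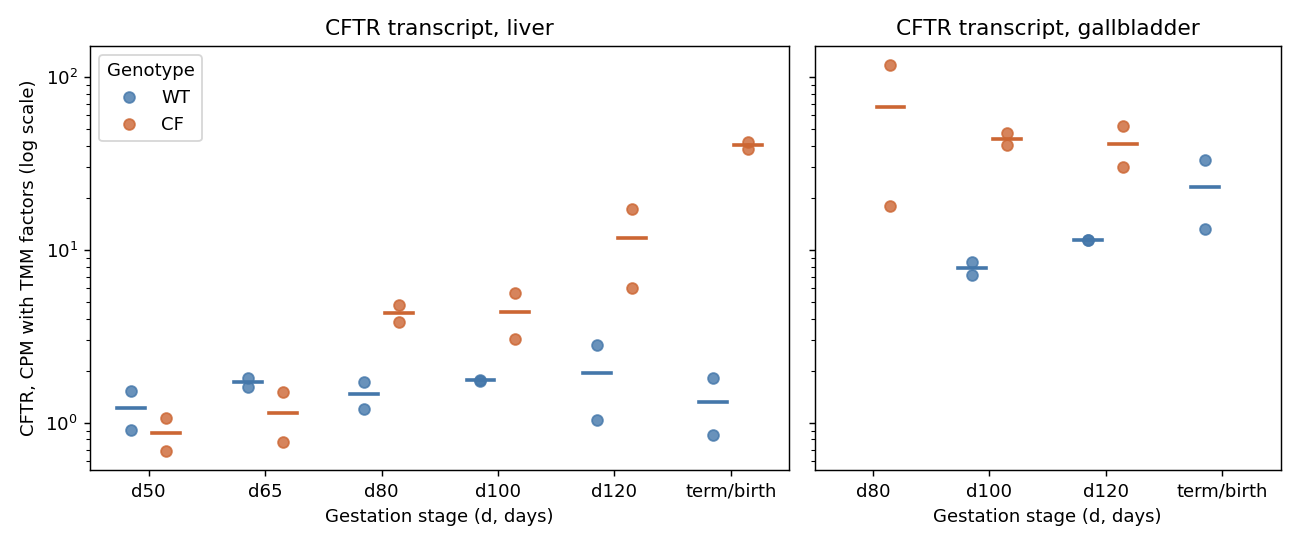
CFTR level in CPM on a log axis for each library of liver and gallbladder by stage, with points for single libraries and bars for the mean of the 2 libraries of a group. CF livers lie above WT livers from d80 on, reaching 40.3 CPM at birth against 1.33 CPM at WT term.

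Across the 5 fetal stages of liver, the genes named here were picked by size of change, and no theme among them was tested. TMPRSS2, an epithelial membrane serine protease, was 4.57-fold higher in CF (log2 2.19 ± 0.24, adjusted p = 6.79e-05), and its lowest CF library, 2.77 CPM, lay above its highest WT library, 2.67 CPM. HSPB8, a small heat shock protein, was 3.08-fold higher (log2 1.62 ± 0.22, adjusted p = 0.000397), again without overlap between the 10 WT libraries (up to 24.5 CPM) and the 10 CF libraries (from 27.7 CPM). Both libraries share a donor-number stem in WT at d50, d80, d100 and d120 and in CF at d65 and d80. The 10 libraries per genotype are therefore not shown to be 10 animals. APOL3, an apolipoprotein L, was 3.10-fold higher, at 89.2 ± 30.9 CPM against 31.3 ± 19.7 CPM (n = 10 each), and RDH16, a retinol dehydrogenase, was 3.04-fold higher. CLDN6, a tight junction claudin of fetal tissues, was at 6.32 ± 4.06 CPM in CF and 1.85 ± 0.825 CPM in WT. The remaining genes named on the higher side were MESP2, AMY2B, FOLR3, SCG3 and SYNPO, with log2 changes between 2.99 ± 0.53 for MESP2 and 1.55 ± 0.27 for SYNPO. Most of these genes did overlap: of the 10 WT libraries, 10 lay inside the CF range for SCG3, 8 for SYNPO, 7 for AMY2B, 4 for RDH16, 3 for CLDN6, 2 for APOL3 and 1 each for MESP2 and FOLR3. For FOLR3 a further WT library, at 16 CPM, lay above all CF libraries (up to 14.8 CPM).

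Lower in CF fetal liver were CA3, a carbonic anhydrase, at 63.8 ± 48.5 CPM against 175 ± 68 CPM (log2 -2.02 ± 0.24, adjusted p = 0.000132), and BHMT2, a methyltransferase of methionine metabolism, at 1.14 ± 0.982 CPM against 7.36 ± 3.62 CPM without overlap (adjusted p = 0.00722). SLC5A11, a sodium-coupled inositol transporter, was lower 5.46-fold (log2 -2.45 ± 0.34, adjusted p = 0.000576). EEF1AKMT2, CLRN3, BEX5, TNNT1, CEL and CERS4 completed the named genes, with log2 changes from -2.03 ± 0.49 for CERS4 to -4.25 ± 0.82 for CEL. Of the 10 WT libraries 7 lay inside the CF range for CERS4, 3 each for CA3 and TNNT1, 1 each for SLC5A11, CLRN3, BEX5 and CEL and 0 for EEF1AKMT2. For CERS4 a further WT library, at 0.861 CPM, lay below all CF libraries (from 0.877 CPM). RPS3A, a protein of the small ribosomal subunit, had the largest named change (log2 -7.76 ± 1.08, adjusted p = 0.000547), but its WT libraries ranged from 0.337 to 934 CPM and 4 of the 10 lay inside the CF range of 0.137 to 1.51 CPM. Of the 20 named genes, SCG3 and CERS4 lost the call when any of several single libraries was left out, and the other 18 kept it throughout. Where a pair shares a stem, leaving out 1 library keeps the other, so this does not test whether such a pair is 1 animal. With 1 unit per stem 72 genes were called in all (below), and which of the 18 were among them is not given here.

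In all, 420 of 16508 genes differed in the fetal liver mean, 141 higher and 279 lower in CF, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The count was 272 without WT d80 replicate 2, 72 with 1 unit per donor-number stem and 898 with the DESeq2 Wald test. The fetal liver libraries had from 14577 (CF d65) to 16194 (CF d120) tested genes above 0, and a detection difference was not separated from genotype.

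Among the gene lists, markers of cholangiocytes, the epithelial cells of bile ducts, leaned higher in CF fetal liver (median log2 0.289 over 22 genes, adjusted p = 0.000773, camera). The adjusted p was 0.965 with an estimated correlation. KRT7, a bile duct keratin, was the 1 member higher (log2 1.49 ± 0.20, adjusted p = 0.000518), SLC5A1, a glucose transporter, was the 1 member lower (log2 -2.54 ± 0.50, adjusted p = 0.0101), and 20 were not called. Adjusted over the list alone 5 were higher and 1 lower. With 1 unit per stem KRT7 was at log2 1.36 with an adjusted p of 0.235, the highest of its 27 alternatives, which began at 2.35e-10. SPP1 and ELF3 had log2 values of 1.22 ± 0.38 and 0.57 ± 0.16 and missed the threshold (adjusted p = 0.105 and 0.0665).

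Blood cell lists leaned lower in CF fetal liver, an organ that makes blood cells before birth. The megakaryocyte list had a median of -0.292 over 13 genes (adjusted p = 0.000495), with PF4, platelet factor 4, as its 1 lower member at log2 -0.49 ± 0.11 and 2 lower when adjusted over the list alone. PF4 lost its call without WT d80 replicate 2 and with 4 other single libraries left out. Granulocyte genes had a median of -0.34 over 15 (adjusted p = 0.0177), with FCN1, a ficolin, lower at log2 -1.29 ± 0.20 over all genes and over the list alone. Erythroid genes had a median of -0.195 over 26 and cell cycle genes -0.21 over 32 (adjusted p = 0.0211 and 0.000773), with 0 members called by edgeR over all genes or adjusted over the list alone. MKI67 was at log2 -0.66 ± 0.22. Genes of the unfolded protein response had a median of 0.104 over 23 (adjusted p = 0.0211), also with 0 members called either way. Each of these lists had an adjusted p of 0.965 with an estimated correlation. The extracellular matrix list was not called, with a median of 0.008 and 0 of 36 members past the threshold either way, and neither were the ion and bicarbonate transport list (1 of 29 higher, the purinergic receptor P2RY2 at log2 1.22 ± 0.23) and the mucin list (0 of 18).

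**Figure D2:**
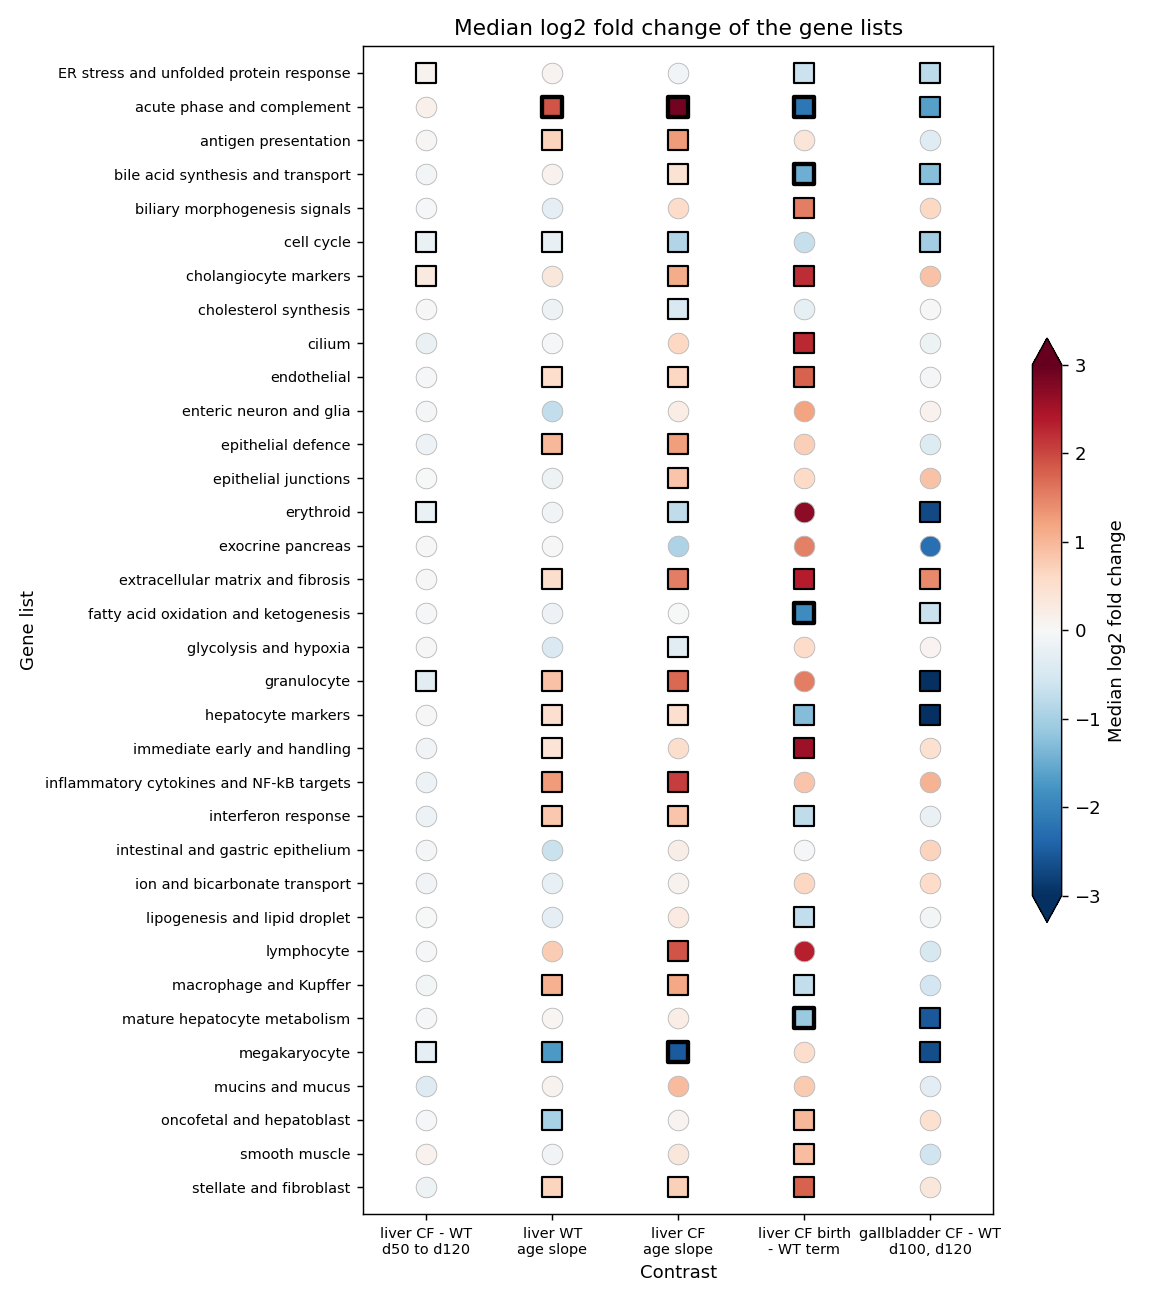
Median log2 fold change of each of the 34 tested gene lists (colour) in 5 contrasts, with a square where the camera adjusted p was under 0.05 and a thick edge where it was also under 0.05 with an estimated correlation. Acute phase genes rose with age in both liver genotypes, with medians of 1.891 in WT and 2.903 in CF, and kept a thick edge there.

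Single fetal stages of liver rest on 2 libraries per genotype and gave from 0 to 273 calls. At d50 edgeR called 0 genes, with 372 at an unadjusted p under 0.05 and 27 by DESeq2. Leaving out 1 library gave 1 call for each WT library and for CF replicate 2 and 8 for CF replicate 1. At d65, 38 genes were higher and 235 lower in CF. The CF d65 libraries had 14652 and 14577 tested genes above 0, against 16099 and 15445 in WT d65, and a detection difference was not separated from genotype. C5, a complement protein, was lower by log2 -2.83 ± 0.32 and UGT1A1, the enzyme that conjugates bilirubin, was at 0 CPM in CF and 12.5 ± 0.718 CPM in WT, at least 380-fold lower. SPOCK1, AP3B2, NESP55 and SUSD2 were also lower, and COL23A1, PYROXD1, PKIB and FAM19A3 were higher. The d65 count was 35 and 806 without WT replicates 1 and 2 and 92 and 42 without CF replicates 1 and 2. Of the genes named for this stage only NPM1 (below), C5, UGT1A1, NESP55 and SPOCK1 kept their calls in all 4 cases. With DESeq2 size factors the d65 calls were 60 higher and 193 lower.

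At d80, 5 genes were higher and 7 lower in CF, among them KRT7 (log2 2.96 ± 0.48, adjusted p = 0.023), TMPRSS2 (log2 3.81 ± 0.59) and PARP3 on the higher side and CCDC141, MAP2, ARPP19, COPG2 and the collagen COL16A1 (log2 -1.82 ± 0.31) on the lower side. The libraries of each d80 pair share a donor-number stem, so whether d80 compares more than 1 animal per genotype is not known. The d80 count was 2 without WT replicate 2, 6 without CF replicate 2 and 18 without CF replicate 1, and each of these 8 genes lost its call in 1 or more of these cases. At d100, 5 were higher, including APOL3 at 88.6 ± 16.8 CPM against 16.8 ± 2.16 CPM and RDH16 (log2 2.46 ± 0.41), and 2 were lower, including DDX58, a cytoplasmic RNA sensor also known as RIG-I (log2 -2.57 ± 0.44, adjusted p = 0.0387). Without any 1 of the 4 libraries the count was 2 and these 3 genes were not called. NPM1, nucleophosmin, was higher in CF at d65 (log2 4.78 ± 0.32), d80 (log2 3.62 ± 0.30) and d100 (log2 4.42 ± 0.32), kept its call in every leave-out at these stages, and had WT levels of 3.21 ± 0.0572, 4.72 ± 0.109 and 2.83 ± 0.577 CPM there against 83.43 ± 24.96 and 48.1 ± 6.12 CPM in WT at d50 and d120. Without TMM factors, 8 of the 12 WT liver libraries held 1.15 to 4.39 CPM of NPM1 and all other liver libraries 41.4 CPM or more, an all-or-none pattern by stage within WT, so the difference is not given as one of genotype alone.

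At d120, 4 genes were higher in CF liver, including CPEB1, a regulator of mRNA translation (log2 1.47 ± 0.22, adjusted p = 0.0202), and FAM35A (log2 2.33 ± 0.38). The count was 0 without WT replicate 2 and 1 without any other d120 library, with neither gene called. CYP7A1, the rate-limiting enzyme of bile acid synthesis, stood at 10.1 ± 4.97 CPM in CF and 0.223 ± 0.175 CPM in WT and missed the threshold (adjusted p = 0.0607), as did the glucose transporter SLC2A1 at log2 -1.48 ± 0.27 (adjusted p = 0.0574). In list tests added after the data were seen, erythroid, cell cycle and megakaryocyte lists had medians of -0.864, -0.709 and -0.993 and the cholangiocyte and epithelial junction lists 0.53 and 0.87, with 0 members called by edgeR. Adjusted over the list alone 7, 0 and 6 were lower and 4 and 2 higher. Their adjusted p ran from 5.98e-10 to 0.000508, and from 0.502 to 0.661 with an estimated correlation. Over all genes at d120, 2358 had an unadjusted p under 0.05 and DESeq2 called 310.

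Liver genes of systemic defence rose with fetal age in both genotypes. In WT the acute phase and complement list had 18 of 25 members higher toward d120 and 0 lower, 20 and 0 when adjusted over the list alone (median log2 1.891, adjusted p = 1.09e-29), and its call held with an estimated correlation (adjusted p = 0.000445). Examples were C2 (log2 3.20 ± 0.26), C3 (log2 2.89 ± 0.27), both complement proteins, and FGL1, a fibrinogen-like hepatokine (log2 7.92 ± 0.60). In CF the list had 22 higher and 1 lower both ways (median 2.903, adjusted p = 4.83e-22; 0.00163 with an estimated correlation). C3 was at log2 3.25 ± 0.27 and C5 at log2 3.73 ± 0.29. PRG4, CR2 and CD5L, the last a product of resident macrophages, rose in both, by log2 9.60 ± 1.15 and 10.75 ± 1.23 for PRG4. S100G, a calcium-binding protein, was at log2 -6.26 ± 0.99 in WT and -10.44 ± 1.18 in CF.

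Megakaryocyte genes fell with age. In CF 8 of 13 were lower, 13 when adjusted over the list alone (median -2.515, adjusted p = 6.79e-14, and 0.02 with an estimated correlation). TUBB1, a platelet tubulin, was at log2 -3.21 ± 0.23 and PF4 at log2 -3.33 ± 0.24. In WT 7 were lower both ways (median -1.718, adjusted p = 6.97e-10, 0.0638 with an estimated correlation). PF4 was at log2 -2.47 ± 0.23. Macrophage genes rose, 13 of 22 in WT and 12 in CF, 17 and 19 when adjusted over the list alone, with C1QA at log2 1.53 ± 0.24 in WT and MSR1 at log2 2.56 ± 0.26 in CF (adjusted p = 2.9e-13 and 1.7e-10; 0.0638 and 0.0636 with an estimated correlation). The oncofetal list had 5 of 21 members lower and 1 higher in WT, 9 and 1 over the list alone (adjusted p = 0.00109; 0.364 with an estimated correlation), including AFP, alpha-fetoprotein, at log2 -3.41 ± 0.60, and LIN28B at log2 -2.97 ± 0.52. AFP lost its call without WT d120 replicate 2.

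Matrix genes and biliary markers were called as lists with age in CF liver, and matrix genes, with fewer members called, in WT. In CF, of 22 cholangiocyte markers 10 rose and 1 fell, the same numbers adjusted over the list alone (median 1.102, adjusted p = 0.000437, and 0.284 with an estimated correlation). KRT7 was at log2 2.23 ± 0.41, ANXA4 at log2 1.73 ± 0.25 and KRT19 at log2 -2.24 ± 0.47. KRT19 lost its call without CF d120 replicate 2. In WT the list was not called (median 0.333, adjusted p = 0.331, 0.83 with an estimated correlation), with 0 higher and KRT19 lower at log2 -1.97 ± 0.47, a call lost without WT d50 replicate 2 or either WT d120 library. In CF, of 36 extracellular matrix genes 18 rose, 20 up and 1 down over the list alone (median 1.525, adjusted p = 4.8e-08, 0.284 with an estimated correlation). COL6A3 was at log2 2.16 ± 0.32 and COL3A1 at log2 2.26 ± 0.35. In WT 7 rose and 1 fell, 11 and 1 over the list alone (median 0.532, adjusted p = 3.39e-05, 0.5 with an estimated correlation). COL6A3 rose there by log2 1.49 ± 0.31 and COL3A1 by log2 1.57 ± 0.34. Both lost this call without WT d120 replicate 2, COL6A3 also without WT d50 replicate 1 and COL3A1 without WT d50 replicate 2. Bile acid genes of the CF slope included CYP7A1 at log2 8.90 ± 1.16 and SLC10A1, the bile acid uptake carrier, at log2 4.03 ± 0.44, with 9 of 29 members higher and 1 lower, 10 and 2 over the list alone (adjusted p = 0.00364; 0.284 with an estimated correlation). In WT the bile acid list was not called (adjusted p = 0.496, 0.83 with an estimated correlation). Cell cycle genes had 10 of 32 lower in CF, 20 over the list alone (median -0.893, adjusted p = 4.59e-10, 0.284 with an estimated correlation), among them MCM6 at log2 -0.97 ± 0.24, whose call was lost without CF d50 replicate 1 or CF d120 replicate 2. In WT their median was -0.22 (adjusted p = 0.015, 0.779 with an estimated correlation) with 0 members called either way.

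The CF slope called 1417 genes up and 1314 down, against 527 and 265 for WT. The CF total of 2731 became 672 without CF d50 replicate 1, 893 without CF d120 replicate 1 and 1061 without CF d120 replicate 2. The WT total of 792 became 456 and 308 without WT d120 replicates 1 and 2 and 416 without WT d50 replicate 1. Tested genes above 0 in CF liver were 15773 and 15945 at d50, 14652 and 14577 at d65 and 16194 and 16037 at d120. Detection was not separated from age. The difference between the slopes itself called 1 gene by edgeR, LOC105609898, an uncharacterised locus named after its values were seen (log2 3.86 ± 0.52, adjusted p = 0.0118). Its count was 0 without WT d120 replicate 2 or CF d120 replicate 2, 4 without WT d65 replicate 2 or CF d80 replicate 1, and 2 without any 1 of WT d120 replicate 1, WT d50 replicate 2 and the 4 CF libraries of d50 and d65. C5 and TUBB1 had differences of log2 2.17 ± 0.38 and -1.49 ± 0.29 with adjusted p of 0.116 and 0.134. In the list tests 11 lists differed in slope, 0 of them with an estimated correlation, for instance the megakaryocyte list (median -0.896, adjusted p = 4.01e-06, 0.581 with an estimated correlation; 4 members lower over the list alone) and the cholangiocyte list (median 0.781, adjusted p = 0.00952, 0.727 with an estimated correlation; 3 higher).

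At the end of gestation the CF and WT libraries differed most within liver, with 2802 genes higher and 2767 lower in CF birth than in WT term. The WT term libraries carry library numbers apart from all other liver libraries, so the differences of this contrast are not shown to be effects of genotype. The CF birth pair had the lowest rank correlation of the liver pairs, 0.937. The list tests of this contrast were added after the data were seen. Enzymes of fatty acid oxidation and ketone production were lower in CF: 23 of 28 fell and 0 rose, over all genes and over the list alone (median -1.876, adjusted p = 1.01e-13, and 0.0447 with an estimated correlation). ACAA2 was at log2 -2.43 ± 0.24. Acute phase and complement genes had 20 of 25 lower and 1 higher both ways (median -2.161, adjusted p = 6.92e-10, 0.0422 with an estimated correlation). C3 was at log2 -3.22 ± 0.32. Bile acid genes had 17 of 29 lower, 18 over the list alone (median -1.476, adjusted p = 2.58e-08, 0.0447 with an estimated correlation). SLCO1B3, a bile acid carrier, was at log2 -4.65 ± 0.50 and HSD17B4 at log2 -2.35 ± 0.19. Metabolic genes of mature hepatocytes had 17 of 29 lower and 1 higher both ways (median -1.117, adjusted p = 2.93e-07, 0.0422 with an estimated correlation). UGT2B7 was at log2 -7.30 ± 0.98. ALB, albumin, stood at 71670 ± 2360 CPM at WT term and at 28480 and 4272 CPM in the 2 CF birth libraries, and the hepatocyte marker list had 17 of 28 lower, 20 over the list alone (adjusted p = 1.2e-06; 0.428 with an estimated correlation).

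Higher at CF birth than at WT term, with the same limit of a possible batch, were genes of matrix, vessels and bile ducts. The extracellular matrix list had 24 of 36 higher and 1 lower, 25 and 1 over the list alone (median 2.358, adjusted p = 1.54e-11, 0.285 with an estimated correlation), including the collagen COL6A3 at log2 5.05 ± 0.41, ELN, elastin, at log2 4.56 ± 0.47 and the protease inhibitor TIMP1 at log2 2.75 ± 0.32. Cholangiocyte markers had 11 of 22 higher and 2 lower, 13 and 4 over the list alone (median 2.225, adjusted p = 0.0005, 0.341 with an estimated correlation), including KRT7 at log2 5.37 ± 0.53 and the transcription factor SOX9 at log2 3.93 ± 0.47. Endothelial genes had 19 of 23 higher, 20 over the list alone (adjusted p = 2.34e-08; 0.285 with an estimated correlation). VWF was at log2 4.22 ± 0.45. Markers of stellate cells and fibroblasts had 13 of 22 higher and 1 lower, 14 and 1 over the list alone (adjusted p = 1.79e-05; 0.345 with an estimated correlation). The lower one was LRAT, which stores retinol in stellate cells, at log2 -6.08 ± 0.96. Biliary morphogenesis genes had 8 of 22 higher and 3 lower, 9 and 3 over the list alone (adjusted p = 0.0441; 0.431 with an estimated correlation). JAG1, a Notch ligand, was at log2 2.25 ± 0.27 and NOTCH2 at log2 -1.97 ± 0.25. Immediate early genes, which respond to handling, had 18 of 30 higher, 22 over the list alone (adjusted p = 6.55e-09; 0.0896 with an estimated correlation). NR4A1 was at log2 5.49 ± 0.60.

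Other large differences at the end of gestation were CYP1A1, a xenobiotic-metabolising enzyme, at 0 CPM in CF birth and 76 ± 62.6 CPM at WT term, at least 3250-fold lower, and ADH1C, an alcohol dehydrogenase, at 0.0165 ± 0.0233 CPM and 124 ± 51.2 CPM. CYP26A1 and BSP5L were also at 0 CPM in CF. MCP-3, FATE1, RIMBP2, MMP12 and LAD1 were higher in CF. LAD1 was at 26.6 ± 13.1 CPM against 0.0492 ± 0.0158 CPM. Its call was lost without either WT term library. The total of 5569 calls became 3536 without WT term replicate 1. The CF birth libraries stood apart from all other liver libraries in scaling, with TMM factors of 1.475 and 2.04 against 0.78 to 1.358 elsewhere, and genotype and possible batch coincide here.

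Matrix genes leaned higher in CF than in WT gallbladder samples in the mean of d100 and d120. The extracellular matrix list had 22 of 36 members higher and 0 lower, 25 and 0 over the list alone (median log2 1.453, adjusted p = 4.82e-07, 0.181 with an estimated correlation). MMP14, a matrix metalloproteinase, was at log2 4.68 ± 0.51 (adjusted p = 0.00182). LOX, which cross-links collagen, was at log2 4.11 ± 0.47 (adjusted p = 0.00195) and the collagen COL12A1 at log2 2.41 ± 0.23 (adjusted p = 0.00136). ADAMTS12, a secreted metalloproteinase, stood at 14.1 ± 7.6 CPM in CF and 0.0597 ± 0.119 CPM in WT (n = 4 each). Fibroblast genes FBLN2 and PDGFRB were higher at log2 2.52 ± 0.30 and 2.90 ± 0.41, though their list was not called (4 of 22 higher and 2 lower both ways, adjusted p = 0.556, 0.934 with an estimated correlation). NF-kB targets had 9 of 19 higher and 0 lower both ways without a call for the list (adjusted p = 0.144, 0.736 with an estimated correlation). IL33 was at log2 1.52 ± 0.28 and IL18 at log2 1.63 ± 0.33. The WT libraries of these stages carried liver transcripts at the same time, with a hepatocyte list at 29.1% to 67.5% of its level in WT liver. Across 18717 genes the fold changes of this contrast correlated with the difference between the 2 CF d80 libraries, which differed in detection (Spearman rho 0.56). Dilution by liver RNA and a detection difference were therefore not separated from genotype in the matrix result.

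Those liver transcripts were lower in CF gallbladder in the mean of d100 and d120, though CF d120 replicate 2 was at 31% for the hepatocyte list against 29.6% and 29.1% in WT d120. Of 27 hepatocyte markers 10 were lower and 0 higher, 6 and 0 over the list alone (median -3.546, adjusted p = 9.85e-07, 0.736 with an estimated correlation), including ITIH1 at log2 -2.71 ± 0.38 and TTR, transthyretin, at log2 -4.03 ± 1.03. Mature hepatocyte enzymes had 12 of 27 lower both ways (median -2.548, adjusted p = 2.51e-05, 0.736 with an estimated correlation), such as FBP1 at log2 -2.35 ± 0.38. FABP1, the liver fatty acid binding protein, was at 8.42 ± 12.4 CPM in CF and 460 ± 250 CPM in WT, APOC4 at 0.668 ± 0.917 and 70.3 ± 18.6 CPM, and the acute phase protein ORM1 at 150 ± 300 and 891 ± 606 CPM. ALB took 62.7% and 67.5% of its WT liver level in WT d100, 29.6% and 24.8% in WT d120, 1.58% and 1.28% in CF d100, and 0.099% and 31% in CF d120, as shares of the library totals of 2 tables made separately. Acute phase genes had 10 of 23 lower and 2 higher, 12 and 2 over the list alone (adjusted p = 0.000994; 0.736 with an estimated correlation). HAMP, hepcidin, was at log2 -5.70 ± 1.17. Of the genes of this paragraph, TTR lost its call without WT d100 replicate 1 or either CF d100 library, ORM1 without any 1 of the 4 d100 libraries, and FABP1 and HAMP without CF d100 replicate 2.

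**Figure D3:**
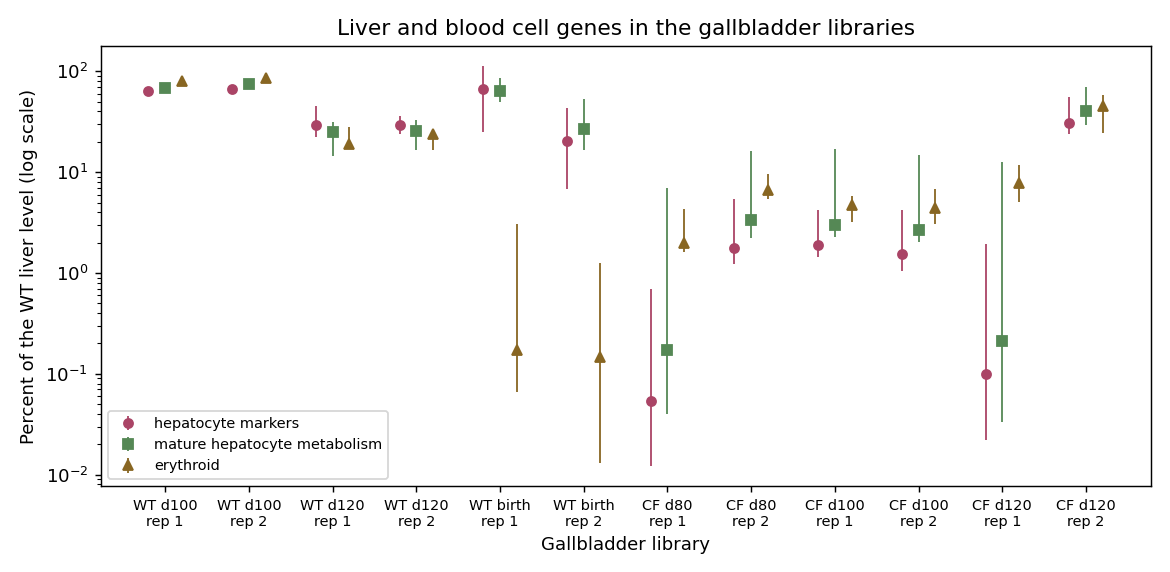
Level of hepatocyte, mature hepatocyte and erythroid genes in each gallbladder library as a percent of their mean level in WT liver of d100 and d120 (log axis), as the median of each list with its quartiles, from shares of library totals without TMM factors. Hepatocyte medians lie at 29.1% or more in the 4 WT libraries of d100 and d120 and at 31% in CF d120 replicate 2, against 1.91% or less in the other CF libraries of these stages.

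Blood cell genes moved with the liver genes. Erythroid genes had 19 of 24 lower in CF gallbladder, 22 over the list alone (median -2.715, adjusted p = 3.36e-09, 0.715 with an estimated correlation). KLF1, an erythroid transcription factor, was at log2 -4.32 ± 0.46 and GATA1 at log2 -3.50 ± 0.48. Granulocyte genes had 10 of 14 lower both ways (adjusted p = 1.78e-05; 0.181 with an estimated correlation). MMP9 was at log2 -4.79 ± 0.47. Megakaryocyte genes had 7 of 12 lower and 1 higher both ways (adjusted p = 0.00183; 0.181 with an estimated correlation). PF4 was at log2 -4.25 ± 0.36. Erythroid genes stood at 80.2% and 85% of their WT liver level in WT d100, 18.9% and 23.9% in WT d120, 4.7% and 4.43% in CF d100, and 7.72% and 45% in CF d120. Cell cycle genes were lower as well, 19 of 32 and 21 over the list alone (median -1.05, adjusted p = 3.91e-05, 0.736 with an estimated correlation). CDC20 was at log2 -1.87 ± 0.30 and MCM7 at log2 -1.50 ± 0.27. Genes of the unfolded protein response had 13 of 23 lower and 1 higher both ways (adjusted p = 0.00315; 0.181 with an estimated correlation), with SDF2L1 at log2 -2.72 ± 0.48 and SEL1L at log2 4.63 ± 0.91, and fatty acid oxidation genes had 11 of 26 lower and 2 higher both ways (adjusted p = 0.00433; 0.736 with an estimated correlation). ACADS was at log2 -1.90 ± 0.24. Bile acid genes had 6 of 27 lower and 3 higher, 4 and 3 over the list alone (adjusted p = 0.0268; 0.934 with an estimated correlation). SLC51B, an exporter of bile acids, was at log2 -3.06 ± 0.38.

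Gene groups of the gallbladder epithelium, and the interferon response and smooth muscle lists, had members in both directions and were not called. Cholangiocyte markers had 7 of 23 higher and 2 lower, 6 and 2 over the list alone (adjusted p = 0.447, and 0.934 with an estimated correlation). PKHD1, fibrocystin, was at log2 4.61 ± 0.93 and KRT19 at log2 -1.65 ± 0.28. Ion and bicarbonate transport genes had 9 of 30 higher and 6 lower, 10 and 8 over the list alone. On the lower side, the potassium channel KCNN4 was at log2 -3.91 ± 0.62 and the carbonic anhydrase CA4 at log2 -1.75 ± 0.30. Mucus genes had 6 of 21 higher and 1 lower, 5 and 1 over the list alone. The 1 lower member was TFF2, a mucus-associated trefoil peptide, at log2 -3.68 ± 0.59. Cilium genes had 3 of 23 higher and 6 lower both ways. FOXJ1, the regulator of motile cilia, was at log2 -2.21 ± 0.27. Interferon response genes had 4 of 28 higher and 11 lower, 5 and 11 over the list alone (adjusted p = 0.0658, 0.736 with an estimated correlation). ISG15 was at log2 -3.99 ± 0.58. Smooth muscle genes had 3 of 19 higher and 4 lower, 2 and 3 over the list alone.

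The remaining named genes of the gallbladder mean on the higher side were UGT1A9-2, NPTXR, PLXNA1, NLGN2, LRRN4, ITPRIPL2, ARSJ, ARNTL2 and ZFP36L2. On the lower side they were TNNI3, TEX33, SRD5A2, MBLA, LRCOL1, BHMT2 and CHIA, a chitinase (log2 -6.10 ± 0.73). UGT1A9-2 was at 0 CPM in WT and 16.1 ± 25.1 CPM in CF (n = 4 each), at least 727-fold higher in the mean, and NPTXR was at least 97.7-fold higher. Of the 20 genes named by size, UGT1A9-2, PLXNA1, NLGN2, ZFP36L2, ORM1, SRD5A2, MBLA, FABP1 and BHMT2 lost their calls when 1 library was left out, NLGN2 without WT d100 replicate 1 and MBLA and BHMT2 without CF d100 replicate 2, for example. In total 4421 genes were higher and 3762 lower in CF. The total of 8183 became 2648 and 3455 without WT d100 replicates 1 and 2, 4887 and 2500 without CF d100 replicates 1 and 2, and 4338 without CF d120 replicate 1. Over genes whose liver level was under 5% of their gallbladder level, 583 of 1903 tested were called, a setting chosen after seeing the data. WT d120 replicate 1 had the fewest tested genes above 0, 15059 against 17302 to 18493 in the other libraries of d100 and d120, and without it and CF d120 replicate 2, also chosen after seeing the data, 3702 genes were called.

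Taken by stage, gallbladder at d100 had 426 genes higher and 796 lower in CF, and at d120 2471 and 1769. The WT d100 pair shares a donor-number stem and the names of the CF d100 pair do not show 2 animals, so whether d100 compares more than 1 animal per genotype is not known. With each d100 pair summed, a setting chosen after seeing the data, the count of the gallbladder mean was 4152 instead of 8183. The list tests by stage were also added after the data were seen. Megakaryocyte genes at d100 had a median of -5.162 (6 of 12 lower, 8 over the list alone, adjusted p = 1.2e-06, 0.0546 with an estimated correlation). TREML1 was at log2 -7.76 ± 0.94 and TUBB1 at log2 -6.04 ± 0.46. The matrix list had 10 of 36 higher at d100 and 15 at d120, 19 and 16 over the list alone (adjusted p = 1.46e-08 and 6.33e-05; 0.139 and 0.75 with an estimated correlation). COL5A1 was at log2 5.31 ± 0.88 at d100 and MMP14 at log2 5.76 ± 0.76 at d120. Hepatocyte genes had medians of -6.232 at d100 and -1.46 at d120 with 1 and 0 members called by edgeR, 4 and 0 over the list alone (adjusted p = 6.94e-07 and 0.000117; 0.666 and 0.962 with an estimated correlation). At d120 ST6GAL1, RYR1, ZNF385A, RANBP10 and NAV2 were at 0 CPM in WT and higher in CF, by at least 426-fold in the mean for ST6GAL1. The CF levels of ST6GAL1 and RYR1, 18.9 ± 23.3 and 15.3 ± 18.9 CPM, rested mostly on 1 of the 2 libraries. ZNF385A, RANBP10 and NAV2 were at 14.5 ± 1.86, 12 ± 5.2 and 11.8 ± 8.37 CPM in CF. TNNI3, CHIA, CDC26, APOC4 and HIGD1B were lower. At d100 GLI3, a Hedgehog pathway transcription factor, and CRISPLD2 were among the higher genes, at 19.7 ± 14.4 and 29 ± 10.4 CPM in CF against 0.0448 ± 0.0633 and 0.147 ± 0.123 CPM. The d100 count of 1222 fell to 0 without either WT library or CF replicate 2 and to 1 without CF replicate 1. The d120 count of 4240 became 252 without WT replicate 1, 320 without CF replicate 1 and 521 without CF replicate 2. Each of the 10 d120 genes named by size lost its call without 1 or more of the 4 d120 libraries, RANBP10 and NAV2 without any 1 of them. ST6GAL1, RYR1 and ZNF385A lost theirs without WT replicate 1, ST6GAL1 also without CF replicate 2, and MMP14 without WT replicate 1. On the lower side TNNI3 lost its call without WT replicate 1 or either CF library, CHIA without either CF library, CDC26 without WT replicate 1 or CF replicate 2, HIGD1B without WT replicate 1 or either CF library, and APOC4 without either WT library or CF replicate 1. The 10 genes named by size at d100 lost theirs as well. With DESeq2 size factors the median of all genes at d100 was 0.13 instead of 0.019 and the calls were 508 higher and 662 lower.

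The change of the genotype effect from d100 to d120 in gallbladder called 0 genes by edgeR, with 2470 at an unadjusted p under 0.05 and 1025 called by DESeq2. TUBB1 and PF4 had the values log2 5.39 ± 0.56 and 4.81 ± 0.66 (adjusted p = 0.084 and 0.125), and CA4 log2 -5.12 ± 0.61 (adjusted p = 0.0979). The count was 616 without WT d120 replicate 2, 162 without CF d120 replicate 1 and 2 without WT d120 replicate 1. In list tests added after the data were seen, the megakaryocyte list differed (median 4.603, adjusted p = 2.92e-07), and its call held with an estimated correlation (adjusted p = 0.0368). 0 of 12 members were called over all genes and 9 were higher over the list alone. Erythroid genes had a median of 4.639 (adjusted p = 3.45e-14, 0.492 with an estimated correlation), with 21 of 24 higher over the list alone.

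From fetal stages to birth, blood cell and proliferation transcripts were lower in WT gallbladder samples. Across 18717 genes the fold changes of this contrast correlated with the difference between the 2 CF d80 libraries, which differed in detection (Spearman rho 0.64). A detection or RNA quality difference therefore stays open for its results. The fetal libraries held liver transcripts, with erythroid genes at 18.9% to 85% and hepatocyte genes at 29.1% to 67.5% of fetal WT liver, and the birth libraries had 0.173% and 0.146% for erythroid and 66.6% and 20.3% for hepatocyte genes. Erythroid genes had 22 of 24 lower at birth than at d100 and d120, over all genes and over the list alone (median -8.13, adjusted p = 2.05e-13, 0.467 with an estimated correlation). AHSP, the alpha-haemoglobin stabilising protein, was at 0.391 ± 0.415 CPM against 1290 ± 617 CPM and HBM at 0.107 ± 0.151 against 418 ± 194 CPM. Cell cycle genes had 26 of 32 lower, 28 over the list alone (median -2.091, adjusted p = 1.27e-13, 0.467 with an estimated correlation). MCM2, a DNA replication helicase subunit, was at log2 -2.71 ± 0.36. Epithelial junction genes had 14 of 30 higher and 1 lower, 17 and 1 over the list alone (adjusted p = 0.000664; 0.893 with an estimated correlation). The tight junction protein OCLN was at log2 2.61 ± 0.43. Cholangiocyte markers had 11 of 23 higher, 12 up and 1 down over the list alone (adjusted p = 0.0134; 0.893 with an estimated correlation), with PKHD1 at log2 4.68 ± 1.00, and matrix genes had 13 of 36 lower and 3 higher, 17 and 3 over the list alone (adjusted p = 0.000507; 0.467 with an estimated correlation). COL14A1 was at log2 -2.78 ± 0.42. MUC1, a membrane mucin, was at log2 3.09 ± 0.31 and CA4 at log2 2.83 ± 0.34. ACSM1, NOX1, ACSM2B and SLC34A2 were higher at birth, and EPB42, KRT17 and HEMGN lower. The 5074 calls became 164 and 185 without WT d100 replicates 1 and 2, 41 and 120 without birth replicates 1 and 2, and 1920 without WT d120 replicate 1. Without birth replicate 1, 11 of the 127 genes called among list members and named genes kept their calls.

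Within CF gallbladder, the step from d80 to d100 and d120 called 1 gene by edgeR, CST6, cystatin M (log2 -3.93 ± 0.35, adjusted p = 0.027), at 53.3 ± 3.65 CPM at d80 and 3.54 ± 0.95 CPM later (n = 4). It was named after its values were seen. COL6A2, HMCN2 and COL5A3 had log2 values of 1.96 ± 0.35, 5.09 ± 0.66 and 2.13 ± 0.37 and missed the threshold, each with an adjusted p of 0.208. Matrix genes had a median of 0.782 (adjusted p = 0.000186, 0.77 with an estimated correlation) with 0 of 36 members called by edgeR and 2 higher over the list alone, and fatty acid oxidation genes had a median of -0.68 (adjusted p = 6.36e-05, 0.82 with an estimated correlation) with 0 called and 8 of 26 lower over the list alone. DESeq2 called 836 genes and 3137 had an unadjusted p under 0.05. The CF d80 libraries differed from each other in detection, with 16253 and 18437 tested genes above 0, and the count was 6697 without CF d80 replicate 2, 0 without either CF d100 library or CF d120 replicate 1, and 2 without CF d120 replicate 2. CST6 kept its call only without CF d80 replicate 2.

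Genes called in both tissues were more than chance gives on the lower side but not on the higher side. Among 15356 genes tested in both, 23 were higher in CF in both the fetal liver mean and the gallbladder mean, against 31.4 by chance (odds ratio 0.674, 0.41 to 1.07, two-sided Fisher's exact test, p = 0.0998). That overlap lay below chance at an adjusted p under 0.1 (odds ratio 0.67, Fisher's exact p = 0.0122) and at an unadjusted p under 0.01 (0.562, Fisher's exact p = 0.000461). Lower in both were 76 genes, BHMT2 and RPS3A among them, against 53.4 by chance (odds ratio 1.62, 1.22 to 2.14, Fisher's exact p = 0.000792). The liver values of RPS3A are in doubt (below). The odds ratio was 1.27 at an adjusted p under 0.1 (Fisher's exact p = 0.0254), and at an unadjusted p under 0.01 the excess was lost (1.11, Fisher's exact p = 0.333). The WT gallbladder libraries held hepatocyte genes at 29.1% to 67.5% of their WT liver level, content that can lower liver genes such as BHMT2, CA3 and LBP in the gallbladder contrast, and the overlap was not corrected for it. Some animals gave both tissues, and genes are not independent replicates.

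RPS3A was abundant in gallbladder of both genotypes, at 641.4 ± 150.1 CPM in CF d100 and 3056 ± 199.9 CPM in WT d100. It was called lower in CF in the gallbladder mean as well (log2 -2.89), and so counts among the genes lower in both tissues. In liver it stood at 0.125 ± 0.0101 CPM in CF birth and 538 ± 95.2 CPM at WT term, and in WT d80 liver at 0.958 ± 0.0711 CPM.

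**Figure D4:**
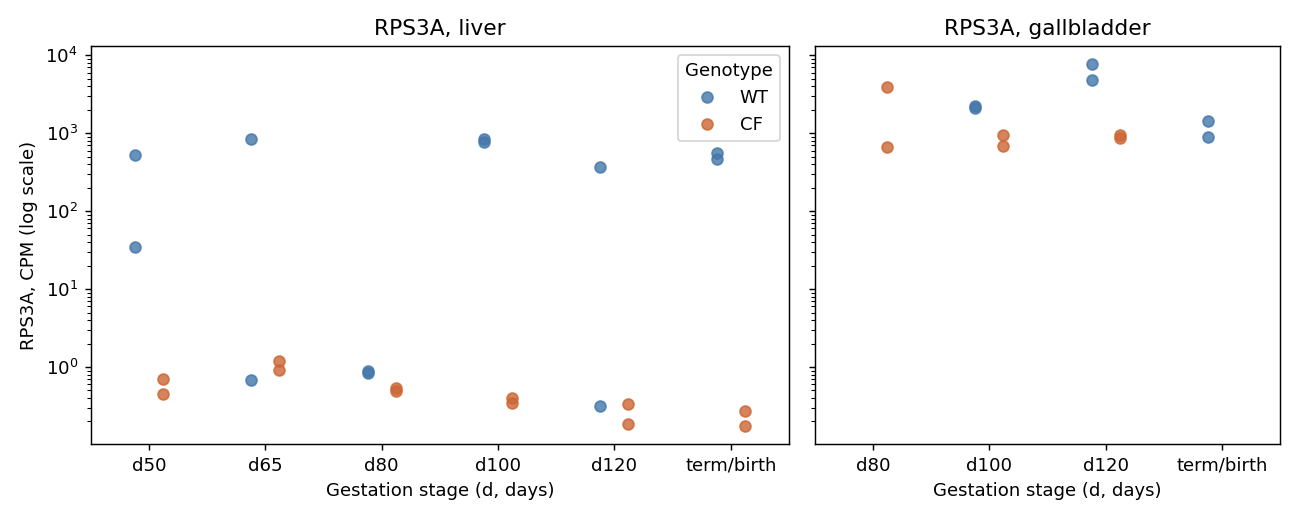
RPS3A level in CPM without TMM factors, on a log axis, for each library of liver and gallbladder by stage and genotype, with a point per library. All CF liver libraries lie at or under 1.18 CPM, as do 4 of the 10 fetal WT liver libraries, while gallbladder libraries of both genotypes lie at 664 CPM or more.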

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

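The tests of liver tissue in the WT gallbladder samples, of a detection difference between libraries, of CFTR against other bile duct markers, of RPS3A and the list tests of the d120 minus d100 difference were chosen only after the result was seen. The dilution test was chosen after the data were seen but before its own result was, and the regroupings of samples were planned. The difference between the CF and WT age slopes in liver passed the threshold for 1 gene, LOC105609898, at log2 3.86 ± 0.52 (adjusted p = 0.0118), which changed by log2 -3.10 in WT (adjusted p = 0.000126) and by log2 0.76 in CF (adjusted p = 0.138). It lost that call without WT d120 replicate 2 or CF d120 replicate 2, when the count was 0. The megakaryocyte list differed between d120 and d100 in its genotype effect in gallbladder, with a median of 4.6 on the log2 scale (adjusted p = 2.92e-07, and 0.0368 with an estimated correlation). The erythroid content moved between the same libraries, from 80.2% and 85% of WT liver in WT d100 to 18.9% and 23.9% in WT d120, and from 4.7% and 4.43% in CF d100 to 7.72% and 45% in CF d120. In simulated data 1 of 20 unchanged lists was called in this contrast and 0 of 20 in each other one. The simulated genes were drawn independently of one another, so this does not test the preset correlation for lists whose members move together.

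Hepatocyte and erythroid genes were lower and matrix genes higher in CF than in WT gallbladder in the mean of d100 and d120. This did not hold for each library: CF d120 replicate 2 had hepatocyte genes at 31% and erythroid genes at 45% of WT liver, against 29.6% and 29.1% and 18.9% and 23.9% in the WT d120 pair. At d120 alone 0 hepatocyte members were called by edgeR, and the list's adjusted p was 0.000117 (0.962 with an estimated correlation). Liver tissue in the WT samples is a candidate explanation for the first part, since the lowest median level of the hepatocyte list in the 4 WT libraries was 29.1% of WT liver and ALB, at 80100 CPM in that liver, reached 62.7% and 67.5% in WT d100. Whether dilution by such RNA alone gives the matrix result cannot be decided by the test made. The 15 members low in liver, rescaled on genes low in liver, had a median log2 change of 1.183 (quartiles 0.361 to 2.817). COL1A1, COL5A1, LOX, MMP14, MMP2 and TIMP3 were past the threshold and 9 members were not. The list had a camera p of 0.00179 (0.0243 with an estimated correlation). Low in liver was judged against a gallbladder level that included the CF libraries. A gene higher in CF passes that filter more easily, so the filter itself favours positive values. All genes in that setting had a median of 0.542. A shift from the filter, or one shared by all genes, was not separated from the change of the matrix members. Smooth muscle genes (5, with 4 lower and 1 higher) had a median of -2.686 there (camera p = 0.0101, 0.132 with an estimated correlation). Stellate and fibroblast genes (10, with 1 lower) had a median of -0.654 and were not called (camera p = 0.0651, 0.528 with an estimated correlation). Dilution alone, moving all alike, does not give members past the threshold in both directions, but this rests on few genes of the same filtered set. A detection or RNA quality difference stays open for the number of calls, since the fold changes correlated across 18717 genes with the difference between the 2 CF d80 libraries (Spearman rho 0.56, Pearson r 0.53; genes are not independent replicates). A difference of the CF gallbladder itself, by genotype, stays open as untested apart from these.

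CFTR transcript in CF liver from d80 to d120 was at log2 1.82 ± 0.31 against WT. These stages were picked because CFTR was higher there, so the difference is no test of its own: the planned fetal mean had an adjusted p of 0.0636, and d80, d100 and d120 had 0.364, 1 and 0.0867. A higher share of biliary epithelial cells in the CF livers cannot be told apart from a change within these cells. The other 22 cholangiocyte markers had a median of 0.466, 1.35 below CFTR, but in stages picked for CFTR; in the planned fetal mean the gap was 0.58, and KRT7 (log2 1.49 ± 0.20) lay above CFTR (log2 0.87 ± 0.24). Whether the disrupted gene makes a more stable or more abundant transcript was not tested, and a biological difference by genotype stays a hypothesis.

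RPS3A was near 0 in the CF livers. A donor variant that removes the transcript from the CF animals is argued against, because the CF animals with both tissues had 0.536 CPM in liver and 3890 CPM in gallbladder at d80 and 0.335 and 865 CPM at d120, as shares of the library total. Reads assigned to a near-identical copy cannot be told apart from other causes: 1 gene, LOC101111988, moved against RPS3A (rho -0.86), but it reached 16.3 CPM against 846 CPM for RPS3A, and 62.7% of 300 drawn genes of like range had such a partner, which makes the test void. The authors' processing of the liver table was not tested, and 4 of 10 fetal WT livers had levels inside the CF range. NPM1, low in 8 of the 12 WT livers (up to 4.39 CPM) and at 41.4 CPM or more in all other livers, leaves the same doubt about the liver table. No biological explanation was tested.

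Other regroupings of the samples were compared with the real one, in additive models for the 2 means and in models with a slope difference or an interaction for the 2 differences. For the fetal liver mean chance is not excluded as the source of the count: 3 of a first 40 regroupings, the real one included, gave as many calls as the real 309, and 4 of 100 did after the draw was extended, on the other side of 5%. The highest other gave 1440, several times the real count, which points to a structure of the samples apart from genotype. In the 3 regroupings with more calls some libraries always fell on the same side. At d50, d65, d80 and d120 those on 1 side had fewer tested genes above 0 than those opposite. At d65 these were CF replicate 2 with 14577 and WT replicate 1 with 16099. This was seen after the fact, and detection was not tested as the cause. For the slope difference the comparison decides nothing, since the real groups gave 0 calls, which 100 of 100 regroupings match by construction; the highest other gave 3276. For the gallbladder mean chance is not excluded. The real groups gave 8565 calls against 0 for the highest other, with 1 of 34 splits as large, but these splits also exchanged genotype labels across stages. Regroupings kept within stage, as in liver, are too few for a share under 0.05 even if the 8 libraries are 8 animals. If each d100 pair is 1 animal, 6 units remain, too few for a share under 0.05, and with these pairs summed 4152 genes were called. For the d120 minus d100 difference the comparison decides nothing: 2 of 34 splits gave as many as the real 6 calls, but the other 1, with 10469, exchanges the genotypes at 1 stage and so counts the genotype effect itself.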

How the results depend on the processing

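The hepatocyte covariate, the restriction to genes low in liver, the removal of 2 doubted libraries, the summed d100 pairs and the list tests of 9 contrasts were chosen after seeing the data; all other settings were planned. Of 11158 alternatives of 973 gene results, 8557 kept their direction and side of the threshold, 2477 fell below it, 119 rose above it and 5 reversed; of 182 alternatives of counts, 92 stayed within 1.5 times and 90 did not. Where nothing else is said, the cause was not tested. With DESeq2 size factors every count stayed within 1.5 times, as did the additive model (309 in the fetal liver mean, 8565 in the gallbladder mean) and the voom fit with the stem as a block in liver (363, consensus correlation 0.033). That fit was not run in gallbladder, where no correlation could be estimated, and TPM pseudocounts were not run because both tables hold counts. No paired analysis was possible because the 1 donor stem given for both genotypes belongs to liver libraries of different stages, WT d65 replicate 2 and CF d100 replicate 2. The labels do not show whether 1 of them is wrong.

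Without the filter on low counts the calls were 6 at liver d50, 546 at d65, 39 at d80, 13 at d100, 41 at d120 and 5 for the slope difference. The DESeq2 Wald test gave 898 for the fetal liver mean, 27, 1234, 221, 47 and 310 for d50 to d120, 178 for the slope difference and 1510 for the WT slope. In gallbladder it gave 5236 at d100, 7856 at d120, 1025 for their difference, 8159 for WT birth and 836 for the CF stages. One unit per stem left 72 calls in the fetal liver mean, with fewer units, and 2170 came with the end of gestation included. The gallbladder mean had 1181 calls with all 6 CF against all 6 WT libraries, 1710 with the hepatocyte covariate, 583 over genes low in liver (fewer genes tested; 0 at d100, 308 at d120), 3702 without WT d120 replicate 1 and CF d120 replicate 2 (0 at d120, 1 library per genotype) and 4152 with the d100 pairs summed. Over the 34 lists in the 7 planned contrasts, list calls went from 82 to 3 of 238 with an estimated correlation; those of the end of gestation and of the d120 minus d100 difference are not among them. The overlap odds ratio for genes higher in CF was 0.67 at an adjusted p under 0.1 (Fisher's exact p = 0.0122) and 0.562 at an unadjusted p under 0.01 (Fisher's exact p = 0.000461), where that for lower genes was 1.11 (Fisher's exact p = 0.333).

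Leaving out 1 library at a time gave these ranges of calls. In liver they were 272 (without WT d80 replicate 2) to 458 for the fetal mean, 1 to 8 at d50, 35 to 806 at d65 (without WT replicate 1 and 2), 2 to 18 at d80, 2 at d100 for each library, 0 to 1 at d120, 3536 (without WT term replicate 1) to 5658 at the end of gestation, 0 to 4 for the slope difference, 308 (without WT d120 replicate 2) to 923 for the WT slope and 672 (without CF d50 replicate 1) to 2789 for the CF slope. In gallbladder they were 2500 (without CF d100 replicate 2) to 8004 for the mean, 0 to 1 at d100, 252 (without WT replicate 1) to 3977 at d120, 0 to 616 for their difference (without WT d120 replicate 2), 41 (without birth replicate 1) to 5695 for WT birth and 0 to 6697 for the CF stages (without CF d80 replicate 2). CFTR in the WT slope ran from -0.21 to 0.99 without WT d120 replicate 2 and 1, and in the CF gallbladder stages from -1.47 to 1.25 without CF d80 replicate 1 and 2. RAB27B at the end of gestation ran from 0.00 to 2.39 (0.00 without CF birth replicate 2). Over genes low in liver FBLN2 and PDPN at gallbladder d100 were at -0.02 and -0.04.

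CFTR kept its calls at the end of gestation and in the CF slope under all 7 and 13 alternatives run, and with 18 alternatives lost that of the gallbladder mean with genes low in liver (log2 0.92, adjusted p = 0.206), without the 2 doubted libraries (2.36, 0.0645) and without WT d100 replicate 1 or 2 or CF d100 replicate 2. None of the 7 alternatives at the end of gestation separates a batch or the share of bile duct cells from genotype. In simulated data the share of 8-fold changes recovered was 100% for the fetal liver mean, 87.9% at liver d65, 72.7% for the gallbladder mean, 25.8% and 18.2% at gallbladder d100 and d120 and 0% for their difference. Of 2-fold changes 82.1% were recovered for the fetal liver mean, 16.4% at liver d50, 10.4% at liver d65 and 0% for the gallbladder mean, where 34.3% of 4-fold changes were. Few or 0 calls at a single stage therefore do not show that smaller changes were absent. At gallbladder d120, 13.3% of the simulated calls were false. The reason for the lower shares in gallbladder was not tested.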

Other observations

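The list results and gene levels given here were read after the data were seen, and no hypothesis of its own was tested in this part. DMBT1, a secreted epithelial defence protein, was higher in CF over the fetal liver stages (log2 0.98 ± 0.20, adjusted p = 0.0109), the 1 member of its list of 14 past the threshold. DDX58 was lower (log2 -1.31 ± 0.19, adjusted p = 0.000818) while its interferon list was not called (adjusted p = 0.0781, and 0.965 with an estimated correlation). TPBG, an oncofetal surface protein, was higher (log2 1.00 ± 0.24, adjusted p = 0.0329); its call was lost without WT d80 replicate 2 and several other single libraries. CEL, a bile salt-activated lipase of the pancreas, was the 1 of 11 exocrine pancreas genes lower in CF fetal liver.

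In CF gallbladder several endothelial genes were higher, with STAB1, a scavenger receptor of sinusoidal endothelium, at log2 3.46 ± 0.33 and CDH5 at log2 1.44 ± 0.26, while the list had 6 of 23 members higher and 2 lower (adjusted p = 0.964, and 0.985 with an estimated correlation). TGFBR2, a receptor for TGF-beta, and NOTCH2 were higher at log2 4.17 ± 0.72 and 2.07 ± 0.37, within a list of biliary morphogenesis with 7 of 23 higher and 2 lower (adjusted p = 0.447, and 0.934 with an estimated correlation). In WT liver between d50 and d120 the antigen presentation genes CD74 and HLA-DMB rose by log2 2.59 ± 0.37 and 1.89 ± 0.27, with 5 of 15 members higher (adjusted p = 8.37e-07, and 0.268 with an estimated correlation). HBZ, an embryonic globin, fell by 4.51 ± 0.63 on the log2 scale in CF liver over the same time, and HBB, an adult globin, rose by log2 5.38 ± 0.98.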
